A study of Cenchrus purpureus with 8 samples.

How the data were processed

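The measurements are RNA-seq libraries from young stem (the uppermost nodes) of 8 entries of a napiergrass germplasm bank, 1 library per entry. Per the labels' protocols, stem pieces were kept in RNAlater, total RNA was extracted with TRIzol, every sample had an RNA integrity number over 6.4 and at least 1000 ng of RNA, and stranded poly(A)-selected TruSeq libraries were sequenced on an Illumina HiSeq. Per the submitters' processing notes, the tools used were FastQC 0.11.8, STAR 2.5.2b, StringTie 2.0.4 and Salmon 0.7.2. The genome build, the annotation, the role of each tool and the treatment of reads shared between transcripts are not given in the sources used here.

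The authors deposited 1 file per library. Per the file headers, each holds for every assembled transcript its length, its effective length in bases (other, not a measure of abundance), its abundance in TPM (normalized by the authors for effective length and depth) and an estimated count of reads. All 8 files list the same 101169 transcripts, with identifiers that group them into 66981 loci. Within a tolerance of 0.001 reads, 99.974% of the estimated counts deposited were whole numbers, and 99.963% were whole in the 18243 loci with 2 or more transcripts. These estimated counts were rounded to whole numbers before any test. Transcripts of 1 locus share exons, so their counts are not independent, and counts summed per locus were tested as an alternative. Among pairs of transcripts of 1 locus with at least 20 reads each in a library, 5.84% had equal counts, where 1.75% would be expected from the number of pairs that differed by 1 read in each direction. Some reads may therefore be counted for more than 1 transcript, in which case totals, sums per locus and the number of separate transcripts are too high. The authors' TPM values were used in no comparison.

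The files do not pair identifiers with gene names or descriptions, and no genome or annotation was used here. The 16 gene lists fixed before the data were examined (monolignol biosynthesis, lignin polymerisation, secondary wall polysaccharides and regulators, primary wall, shikimate pathway, methyl donors, flavonoids, green leaf cells, dividing cells, phloem, epidermis, defence, heat shock, cytosolic ribosome and organelle-encoded RNA) therefore matched 0 transcripts. The gene list tests and the summed abundance of the monolignol list planned on them were not run. The rule for naming transcripts asked for those past the threshold whose groups did not overlap, and at most 2 that rose and 2 that fell if identifiers carried no names. No transcript met it, so the 4 transcripts described were chosen after their values were seen. They are the transcript with the smallest p among those lower in high lignin, the next at an average log2 CPM of at least 1 and over 1000 locus numbers away, and the smallest p from each of 2 loci among those higher.

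The lignin group of each library was taken from the labels: 4 high and 4 low lignin entries. Each library is a different entry, so the replicates are entries. The labels give no repeat of an entry, no batch and no pairing, and the replicate numbers used here only name the libraries. As a check for a library deposited under 2 names, the chi-square of counts per degree of freedom was computed for each pair within a group; it ran from 50.5 to 111, so every library was kept as its own replicate.

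The main test was edgeR's quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3), two-sided, with TMM normalization, the filterByExpr filter, robust dispersion estimates and lignin group as the only term, over all 8 libraries. Benjamini-Hochberg adjusted p-values under 0.05 counted as calls. CPM is the rounded count scaled to the TMM-adjusted library size, and log2 CPM used a prior count of 2. Standard errors are the log2 fold change divided by the square root of F. Single values per library were compared with exact two-sided permutation tests over all relabellings (Python 3.11.15, scipy 1.17.1), where 4 against 4 cannot give a p below 0.0286. The alternatives were DESeq2 1.42.0, limma-voom (limma 3.58.1), RLE and upper-quartile scaling, no filter or a filter of 1 CPM in 4 libraries, an effective-length offset, a test against a 1.5-fold change, sums per locus, and each library left out in turn. Thinning all libraries to the smallest total, 14925390 reads, the fit without robust estimates, DESeq2 without 1 library and shares from the most abundant transcript of each locus were added after seeing the data.

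The fit was tested on simulated data for the 4 against 4 comparison, with 200 transcripts changed by known folds, 50 at each fold. With a low dispersion of 0.05, edgeR recovered 50 of 50 transcripts at each of 4-, 8-, 16- and 64-fold, among 73828 transcripts, with 9 false calls. The second simulation used the spread that edgeR itself fitted to these libraries, among 70832 transcripts. There edgeR recovered 2, 9, 30 and 44 of 50 at 4-, 8-, 16- and 64-fold, with 7 false calls. DESeq2 on the second simulation recovered 18, 38, 45 and 48 of 50 at 4-, 8-, 16- and 64-fold, with 183 false calls.

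Library totals ran from 14925390 to 17997520 reads assigned to transcripts. A count of 0 allows up to 3 reads, or 0.149 to 0.2 CPM per library. Such floors cover counting error only.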

Results

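The young stem transcriptome of napiergrass (Cenchrus purpureus, also called elephant grass), a tall perennial forage grass whose stem lignin limits digestibility, was measured in 8 germplasm entries. The series asks which genes are associated with lignin production, and the entries had been picked beforehand as 4 with high and 4 with low lignin. The high lignin libraries 1, 2 and 3 were entries BAGCE 5, 10 and 82, and library 4 was Pioneiro. The low lignin libraries 1 to 4 were entries BAGCE 7, 32, 96 and 98. The p-values that compare the lignin groups rest on the spread between libraries. No entry was sampled more than once, so differences between entries and variation within an entry cannot be told apart. The p-values from shuffles or random draws of loci take loci, not entries, as the units. Lignin content itself was not analysed here.

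Between 15405987 and 17997520 reads were assigned to transcripts in the high lignin libraries, and between 14925390 and 16970262 in the low lignin libraries. At least 1 read was found for 84299 transcripts in high lignin library 1, although it was the deepest, against 89027 to 93075 in the other 7 libraries. The mean was 89679 ± 3994 transcripts in high lignin and 91722 ± 423 in low lignin (SD, n = 4 each), a difference within the spread of the entries (exact two-sided permutation test, p = 0.429, adjusted p = 0.543 over 9 library measures). The difference, high minus low, went from -2040 to -250 without high lignin library 1 and to -3180 without high lignin library 4. Reads reached 10 or more in all 8 libraries for 49397 transcripts, and 89 transcripts had no read in any.

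A pair of neighbouring loci, MSTRG.65584 with 10 transcripts and MSTRG.65585 with 6, took the most reads, 6.7% and 2.28% of the total over all libraries with their transcripts summed. These shares are too high if reads that fit several transcripts were counted for each of them, which the sources used here do not state. With only the most abundant transcript of each locus kept, the 2 loci took 2.64% and 1.02%. No gene name is given for either. MSTRG.65584 took 5.5% ± 3.71 of the reads in high lignin and 7.98% ± 3.83 in low lignin (SD, n = 4 each; exact two-sided permutation p = 0.371, adjusted p = 0.543). Its share was lowest in high lignin library 1, at 1.58%, and highest in low lignin library 3, at 13.2%. The difference of -2.48 percentage points, high minus low, became -0.724 without low lignin library 3 and -1.18 without high lignin library 1. It was -3.93 without high lignin library 2 and -3.75 without low lignin library 1. MSTRG.65585 took 1.71% ± 0.961 in high lignin and 2.89% ± 1.05 in low lignin (SD, n = 4 each; exact two-sided permutation p = 0.171, adjusted p = 0.543). That difference, -1.18 percentage points, became -0.755 without low lignin library 2. The range between entries within each group was thus wider than the difference between the groups.

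**Figure D1:**
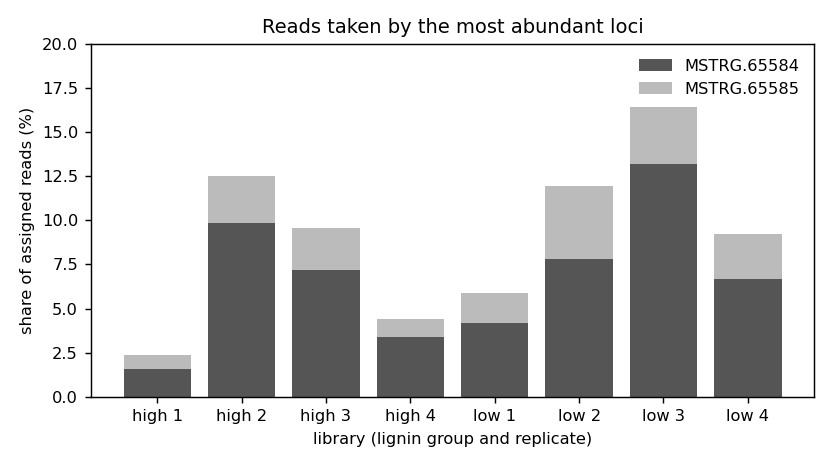
Stacked bars give the percent of each library's assigned reads (y axis) taken by the loci MSTRG.65584 and MSTRG.65585 in the 4 high and 4 low lignin libraries (x axis). MSTRG.65584 ranges from 1.58% in high lignin library 1 to 13.2% in low lignin library 3, and the groups overlap.

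The entries did not separate by lignin group over the whole transcriptome. Spearman's rho between libraries, over 75218 tested transcripts, ran from 0.565 to 0.852, and both extremes were pairs of 1 high and 1 low lignin entry. The mean over the 12 pairs within groups was 0.734 and over the 16 pairs between groups 0.744, so entries of the same group were no more alike than entries of different groups (exact one-sided permutation test, p = 0.6). The mean was 0.719 among high lignin entries and 0.75 among low lignin entries. High lignin library 3 and low lignin library 3 were the most similar pair, at 0.852, and high lignin library 2 also resembled low lignin library 3, at 0.843.

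**Figure D2:**
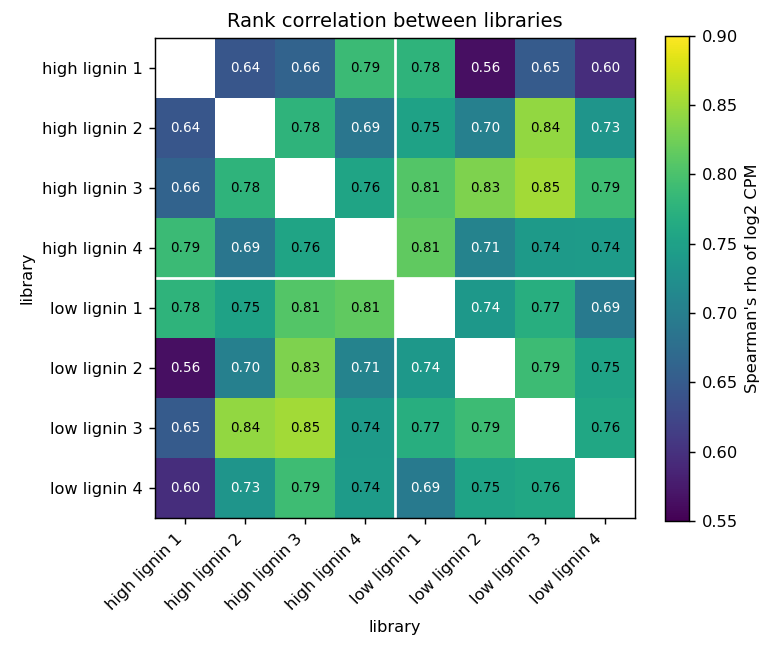
Spearman's rho of log2 CPM over the tested transcripts for every pair of the 8 libraries (both axes), with lines between the lignin groups. The blocks within groups are no warmer than the block between them, and the row of high lignin library 1 holds the lowest value, 0.565.

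The first principal component carried 35.8% of the variance and the second 19.1%. The first set high lignin library 1 apart at a score of -386.3, with high lignin library 4 at -106.7 and low lignin library 1 at -81.6 on the same side. The other 5 libraries, 2 high and 3 low lignin, lay between 87.0 and 166.0. The second component set high lignin library 2 apart at 271.2. Neither component differed between the groups (exact two-sided permutation tests, p = 0.171 for the first and 0.543 for the second, adjusted p = 0.543 for both). Without high lignin library 1, the difference in the first component turned from -154.2 to 45.4, high minus low.

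**Figure D3:**
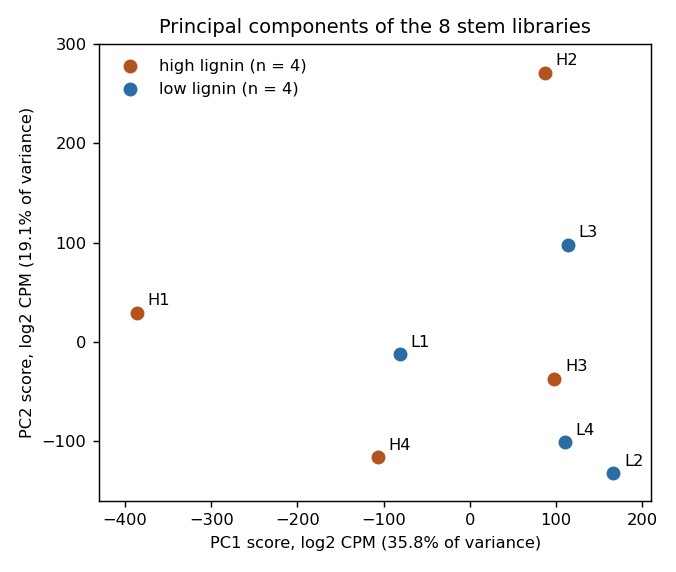
Scores of the 8 libraries on the first (x axis) and second (y axis) principal components of log2 CPM, labelled H for high and L for low lignin with the replicate number. High and low lignin entries are intermixed, and H1, at -386.3 on the first component, lies apart.

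The question of which transcripts differ with lignin group was put to each of the 75218 transcripts, from 46112 loci, that passed the filter. With edgeR's quasi-likelihood test 0 transcripts passed an adjusted p of 0.05, and the smallest adjusted p was 0.709. At an unadjusted p under 0.05 there were 1792 transcripts, 826 higher and 966 lower in high lignin, or 2.38% of those tested. With no difference at all, a share of 0.05 is expected under that threshold, so the 1792 are no excess. That count rests on single libraries: it was 816 without low lignin library 2, 1030 without high lignin library 1, 2781 without high lignin library 2, 3106 without low lignin library 1 and 4672 without high lignin library 3. More were higher than lower in high lignin without high lignin library 2 (1597 and 1184) and without low lignin library 2 (423 and 393). The count was 3077 without a filter and 859 against a 1.5-fold change. Limma-voom also called 0, with 1741 at an unadjusted p under 0.05, 576 higher and 1165 lower. Summing the counts per locus gave 0 of 46894 loci, with 1157 at an unadjusted p under 0.05. DESeq2 had 3506 at an unadjusted p under 0.05 and called 37 transcripts from 24 loci, 3 higher and 34 lower in high lignin, of which 12 had no read in any high lignin library. In all, 1132 transcripts had non-overlapping groups, 494 with every high lignin entry above every low lignin entry and 638 with every one below. That is 1.5% of the tested transcripts, where chance gives 2.86%.

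These counts are limited by the spread between entries. The common biological coefficient of variation was 0.714, and the median 95% interval of a log2 fold change reached 1.33 to either side in limma-voom. In simulated libraries with this spread, edgeR found 2 of 50 transcripts changed 4-fold and 44 of 50 changed 64-fold. Most differences of the smaller size would thus not have been detectable with 4 entries per group. The simulation drew each transcript independently and included transcripts changed by known folds. An adjusted p depends on how many other transcripts have a small p, so recovery there need not carry over to these libraries. MSTRG.59929.1, with a log2 fold change of -11.84, had an unadjusted p of 1.56e-05 and an adjusted p of 0.709 in edgeR. Whether the real libraries were harder cannot be told from these values. The simulation therefore does not show that 64-fold differences would have been found here.

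Reads were present in 1 group and absent from the other for a set of 12 transcripts from 7 loci. They had at least 10 reads in every low lignin library and none in any high lignin library. The opposite set, present in high lignin and absent in low lignin, held 0 transcripts. This criterion was chosen after the values were seen. Reads for the 12 transcripts ran from 11 to 640 per low lignin library. At 4 of the 7 loci the high lignin libraries had no read for any transcript. Of the 12, 9 belonged to 4 loci that form 2 pairs with nearby locus numbers. The first pair lay at numbers 11304 and 11311 and held 4 of the transcripts, and the second lay at 59925 and 59929 and held 5. Among the 35 ways of splitting the 8 libraries into 4 and 4, 8 gave as many such transcripts with both directions summed, and 6 gave as many in the larger direction alone, the lignin split included in both. The count, and how far it lay on 1 side, depended on single libraries. Leaving a library out can only add transcripts, so the 12 stayed in each set below and their direction could not be lost. More transcripts were absent from high than from low lignin in each case, which therefore lends the direction no support. Without high lignin library 3, 16 transcripts, the 12 among them, were absent from high lignin and 11 from low lignin. Without low lignin library 3 these numbers were 35 and 7, and without low lignin library 1 they were 20 and 3. Without high lignin library 4 they were 19 and 1, and without low lignin library 2 they were 16 and 1. Without high lignin library 2 or low lignin library 4, 23 and 20 transcripts were absent from high lignin, and 0 from low lignin in each case. Without high lignin library 1 the numbers stayed at 12 and 0. A minimum of 5 reads gave 20 transcripts and sums per locus gave 6 loci, all absent from high lignin.

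The transcript with the smallest p, MSTRG.59929.1, is 810 bases long and belongs to this set. It had 575, 278, 640 and 230 reads in low lignin libraries 1 to 4 and 0 in all 4 high lignin libraries. Its level was 27.6 CPM ± 13.8 in low lignin (SD, n = 4), with entries from 13.1 to 41.3 CPM. That mean lay 157-fold above the mean floor of 3 reads in the high lignin libraries, 0.176 CPM. The ratio leaves out the spread between entries. The adjusted p of MSTRG.59929.1 was 0.709 in edgeR, 0.966 in limma-voom and 1.17e-16 in DESeq2. MSTRG.11311.3, of 3109 bases, had 83, 220, 57 and 146 reads in low lignin libraries 1 to 4 and 0 in the high lignin libraries. Its level was 8.01 CPM ± 4.83 in low lignin (SD, n = 4), a mean 45.6-fold above the same floor, with entries from 3.68 to 14.7 CPM. Its adjusted p was 0.709 in edgeR, 0.966 in limma-voom and 1.57e-10 in DESeq2. In the same libraries MSTRG.11311.1 had 84, 234, 58 and 156 reads and MSTRG.11311.2 had 79, 220, 51 and 163, nearly the same counts. How reads shared between the transcripts of this locus were divided is not given. They may therefore be 1 signal counted more than once.

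Of the transcripts with more reads in high lignin, MSTRG.32816.1, of 1304 bases, had the smallest p. It was at 35.4 CPM ± 37.1 in high lignin and 0.763 ± 0.737 in low lignin (SD, n = 4 each), a log2 fold change of 5.52 (SE 1.22). It was 4.66 without high lignin library 1 and 6.3 without low lignin library 3. All 4 high lignin entries lay above the 4 low lignin entries, but the high lignin values ran from 4.34 to 83.1 CPM. Its adjusted p was 0.9999 in edgeR, 0.966 in limma-voom and 0.000399 in DESeq2. MSTRG.40095.1, of 1027 bases, was at 4.47 CPM ± 2.83 in high lignin and 0.657 ± 0.24 in low lignin (SD, n = 4 each), a log2 fold change of 2.75 (SE 0.67). Its adjusted p was 0.9999 in edgeR, 0.966 in limma-voom and 0.111 in DESeq2. High lignin library 2, at 0.917 CPM, lay barely above low lignin library 3, at 0.903 CPM.

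**Figure D4:**
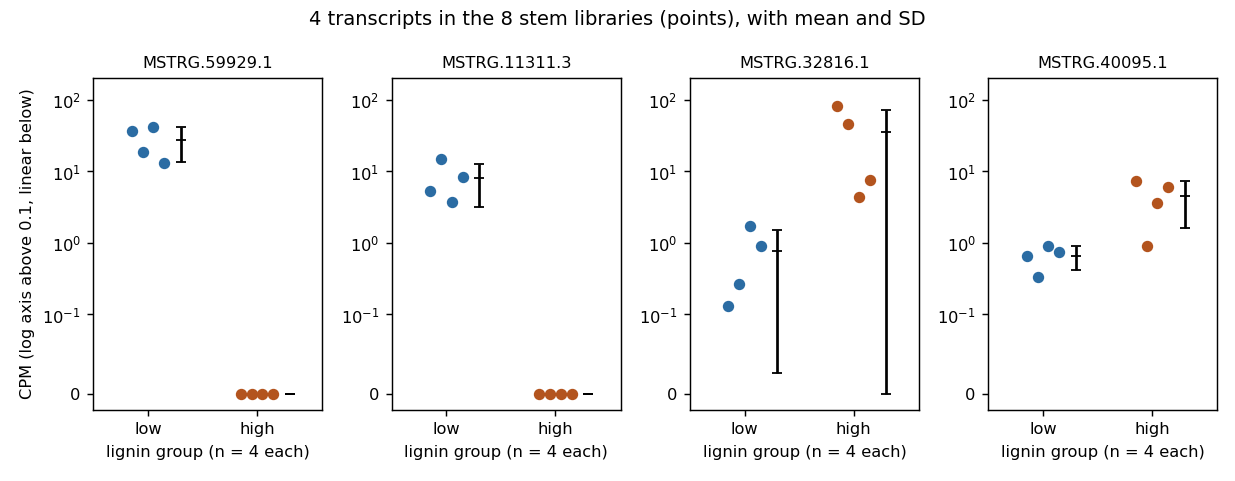
CPM of 4 transcripts (y axis, logarithmic above 0.1 and linear below) in the low and high lignin libraries (x axis, n = 4 each); points are libraries, and bars give the mean and SD, with the lower end held at 0. MSTRG.59929.1 and MSTRG.11311.3 have 0 reads in all 4 high lignin libraries, while the high lignin values of MSTRG.32816.1 spread from 4.34 to 83.1.

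Single entries also lacked transcripts found in the rest. High lignin library 1 lacked any read for 1181 transcripts, at 833 loci, that had at least 10 reads in each of the other 7 libraries. The same count was 287 for high lignin library 2, 25 for library 3 and 32 for library 4. In low lignin it was 14, 169, 142 and 66 for libraries 1 to 4. The reverse, at least 10 reads in a single library and none in the other 7, held for 313 transcripts in high lignin library 2 and for 12 to 89 in the others.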

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

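No paired analysis was possible because each library is a different germplasm entry and the labels give no number that links entries across groups. The count of transcripts past the threshold stayed at 0 in edgeR under RLE and upper-quartile scaling, both other filters, the effective-length offset, the 1.5-fold test, sums per locus, the fit without robust estimates and each left-out library (lowest 0, highest 0), and in limma-voom. DESeq2 called 37, and 50 without high lignin library 1, of which 28 were among the 37. The cause was not tested. In simulated libraries DESeq2 made 183 false calls where edgeR made 7. Their spread was edgeR's own estimate, which may favour edgeR, so this does not show that the 37 are false. With libraries left out, the difference in the first component ran from -207.5 to 45.4 (reversed without high lignin library 1) and in the second from -21.8 to 107.7 (reversed without high lignin library 2). The excess of the rank correlation within over between groups ran from -0.032 to 0.017 around -0.01, positive at 0.005 without low lignin library 1 or high lignin library 2 and at 0.017 without high lignin library 3. None of these passed 0.05. The set of transcripts present in 1 group and absent from the other ran from 12 to 42, both directions summed, with libraries left out, as fewer libraries make the criterion easier to meet, and was 20 with a minimum of 5 reads and 6 with sums per locus, where the unit counted is the locus. The difference in the number of transcripts with at least 10 reads, high minus low, ran from -2940 without high lignin library 4 to 82.6 without high lignin library 1 (exact permutation p = 0.914). The 4 named transcripts kept their direction in every alternative that tested them. This lends the direction no support: they were picked for a small p and their groups did not overlap, so no left-out library could reverse it. With only the most abundant transcript of each locus kept, the difference in the share of reads, high minus low, was -1.01 percentage points for MSTRG.65584 (exact permutation p = 0.4) and -0.483 for MSTRG.65585 (exact permutation p = 0.171). The planned gene list tests and the monolignol sum were not run, since no identifier could be matched to a list.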

Other observations

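The tests of neighbouring loci by shared pattern, of depth, of the relations of the first component to the most abundant loci and other library measures, of transcript use with libraries left out, and the counts of splits for edgeR's transcripts and for the set absent from high lignin were chosen only after the result was seen. The rank correlation within against between groups and the library measures other than the component scores were not among the planned tests either. None of the 32 groups of 4 values tested held a library beyond Dixon's 95% limit.

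Loci with nearby numbers often shared the same set of entries among transcripts that were on in some entries and off in others. A transcript counted here if every library had either 0 or at least 10 reads and 2 to 6 libraries had reads, which gave 1129 loci. Loci with consecutive numbers shared that set in 35 of 74 pairs (47.3%), where shuffling gave 1.77. Sharing fell to 19.6% of pairs 2 to 5 numbers apart, 8.47% at 6 to 10, 5.85% at 11 to 50 and 3.77% at 51 to 200. Each lay above the average of 1000 shuffles (permutation p = 0.001, the smallest they can give, except 0.002 at 6 to 10, where the highest shuffle equalled the 10 pairs observed).

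A candidate explanation, which the files cannot test, is that whole segments of the genome are present, or diverged from the reference, in some entries only, if the locus numbers follow the order along the chromosomes, which the files do not state. Random placement is argued against by 123 sharing pairs up to 50 numbers apart, where shuffles averaged 28.7 and reached 48. At 11 to 50 numbers apart, 50 pairs shared a pattern, against 20.6 in shuffles, and still 50 without the pattern of the lignin split. The shuffles took loci as separate units, although adjacent pieces of a broken gene would carry the same pattern together. The number of sharing pairs could then vary more than in the shuffles, so genes broken into adjacent loci are not excluded. Shared regulation of neighbours and tandem copies that divide reads stay open as well, and neither was tested.

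For the 12 transcripts absent from high lignin, chance is not excluded: with both directions summed, 8 of the 35 splits gave 12 or more, and the highest other gave 22. In the larger direction alone, 6 of the 35 gave 12 or more, and the highest other gave 20. The 37 transcripts called by DESeq2 were matched or exceeded in 26 of the 35 splits, and 1 other split gave 3158. The 1792 transcripts at an unadjusted p under 0.05 in edgeR were matched or exceeded in 25 of 35 splits, with 9998 at the highest other. For edgeR's count of 0 past the threshold the comparison decides nothing, since any split gives at least 0; the value was 0 in 35 of 35 splits, with 0 at the highest other. The split with 9998 and 3158 sets high lignin libraries 1, 2 and 4 with low lignin library 1 against the rest. Every split that kept high lignin libraries 1 and 4 with low lignin library 1 gave 7047 to 9998 and 1314 to 3158. The other splits gave at most 5849 in edgeR and 570 in DESeq2. The libraries thus have a structure that the lignin groups do not follow, and high lignin library 2 is not needed for it. Whether that structure is descent, growth stage or handling could not be settled, since the labels give none of them.

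High lignin library 1 stood apart, with a mean rho of 0.669 with the other libraries against 0.724 to 0.782 for the rest. It was not apart from all of them. Its rho was 0.789 with high lignin library 4 and 0.777 with low lignin library 1, against 0.565 to 0.662 with the remaining libraries. Lower depth is argued against, since its depth ranked 1 of the 8. Loss of long transcripts is argued against too: the rho across transcripts between length and its ratio to the other high lignin libraries was 0.12, so long transcripts were, if anything, better represented, and a loss of them in the other libraries stays open. Of the 833 loci missing from it alone, 18.1% had another within 5 numbers, against 12.5% in random draws (permutation p = 0.001, the smallest that 1000 draws can give), which is consistent with missing or diverged segments but also with genes split into adjacent loci. A difference of genotype, stage or growing conditions of this entry stays open and untested.

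The use of transcripts within loci was tested as a further hypothesis with edgeR's diffSpliceDGE over 15356 loci. It called 1 locus, MSTRG.59925 (11 transcripts tested, adjusted p = 0.0204), and 24 at an unadjusted p under 0.05. With no difference at all, a share of 0.05 of the loci is expected under that threshold, and the 24 lie far below it. The test was thus conservative here, and its few calls do not show that transcript use was alike. MSTRG.59925 also holds transcripts of the set absent from high lignin. High lignin library 1 had no read for any of its transcripts, so the comparison rests on the other 3, with reads for 7 transcripts and 168 to 267 reads summed over them. Without high lignin library 1 the locus was still called (adjusted p = 1.32e-10), and without any of the other 7 libraries 0 loci were called (adjusted p of this locus 0.16 to 1). Of the 35 splits, 8 called at least 1 locus, and the highest other called 8, so chance is not excluded.

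The share of reads in MSTRG.65584 and MSTRG.65585 together rose with the first component across the 8 libraries, Pearson r = 0.84 (exact permutation p = 0.00538) and Spearman rho = 0.79 (exact permutation p = 0.0279). Without low lignin library 3 and high lignin library 1, the farthest from the median share, r was 0.91 (exact permutation p = 0.0292) and rho 0.6 (exact permutation p = 0.242) over 6 libraries. With the group means removed and libraries relabelled within the lignin groups (576 arrangements), r was 0.8 (exact permutation p = 0.033) and the correlation of ranks 0.8 (exact permutation p = 0.0469). Over 8 relations of the component to library measures, the adjusted p was 0.014 for r and 0.0447 for rho, and within the lignin groups 0.066 and 0.0833. For the share of the 100 most abundant transcripts r was 0.83, and for the read-weighted mean transcript length it was -0.81 (exact permutation p = 0.00585 and 0.00702, adjusted p = 0.014 for both). Both measures include the reads of MSTRG.65584 and MSTRG.65585, so they cannot decide whether the relation is specific to these loci. Transcripts of these loci are among those that define the component.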
